A study of Mus musculus with 9 samples.

How the data were processed

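RNA of a mouse bone marrow mesenchymal stromal cell line was sequenced after 24 h with peritoneal fluid (PF) of control mice, PF of mice given TNBS for 3 days, or phosphate-buffered saline. There were 3 groups of 3 libraries, all with 10% serum per the labels. Per the labels, total RNA was isolated with Trizol, with an input of 3 µg RNA per sample, reads were trimmed with cutadapt 1.15 and the genome build was mm10. The aligner, the strand of the libraries and the program that assigned reads to genes are not given in the sources used here.

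The authors deposited 1 table with 21959 genes. Per the file headers it holds FPKM, fragments per kilobase of gene scaled to the assigned fragments of the library, for each library, and the authors computed them before depositing the table. Their scale was checked against exon lengths of GENCODE M21, which gave a length for 21851 genes and no length for 108. The deposited FPKM multiplied by these lengths fell on whole multiples of 1 fragment within a tolerance of 0.01 for 97.2 to 97.3% of values under 1000 fragments, so the number of assigned fragments per library was recovered from the values. The authors also gave, per the file headers, a log2 fold change for each pair of groups, which the authors computed and which lies within 0.0289 of the log2 ratio of the deposited group means. The deposited p-value beside each log2 fold change comes from a test that is not given in the sources used here, and the authors' calls in the table all had p under 0.05 and an absolute log2 fold change of at least 1. These columns and the 3 columns of group means were not used for the tests. The depth was between 17.9 and 25.6 M assigned fragments, at which 1 fragment in 1 kb is an FPKM of 0.0391 to 0.056. The table held 5766 genes at 0 in all 9 libraries.

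Groups, comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. FPKM were transformed as log2(FPKM + 1), and genes with FPKM of at least 1 in at least 3 libraries were tested, which left 10537. All 9 libraries entered 1 linear model in limma 3.58.1 with R 4.3.3, with moderated variances and a mean-variance trend, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. The median standard error of a log2 fold change was 0.0545. The 3 comparisons were TNBS PF with control PF, control PF with PBS, and TNBS PF with PBS. The replicate numbers were not used to pair libraries, since nothing in the labels states what they share. Single values such as the ribosomal share were compared by exact permutation, where 3 against 3 libraries give no two-sided p under 0.1.

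Of 39 gene lists, the 29 with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the residuals. The second setting also reads the camera statistic with the few residual degrees of freedom of the 9 libraries. A call lost in it need not be lost through correlation between genes. For the lists, genes were also adjusted over the list alone. The lists of chondrogenic genes and of markers of macrophages and monocytes, neutrophils, B and plasma cells, T and NK cells, erythroid cells, mast cells and eosinophils, mesothelial cells, endothelial cells and intestinal epithelium had fewer tested members and are given as values where used. The annotation terms in the table with 10 to 300 tested genes, 2261 in number, were tested in the same way.

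Genes named in the text follow a rule: among genes past the threshold whose 2 groups do not overlap and whose symbol is not a predicted or clone name, the 12 largest rises and the 12 largest falls. To these are added up to 4 members of each described list, by largest absolute log2 fold change among members past the threshold or the member of smallest p where none passed, and 10 preset genes (Il6, Ccl2, Cxcl12, Ptgs2, Tnfaip6, Tgfb1, Nfkbia, Isg15, Mki67 and Col1a1). The rule gave 112, 87 and 125 distinct genes in the 3 comparisons. Genes named outside it are said to have been chosen after their values were seen.

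The procedure was tested on simulated data with 200 genes changed. In the comparison of TNBS PF with control PF it recovered 43.3% of genes changed by 0.25 on the log2 scale, 83.6% of those changed by 0.5 and 100% of those changed by 1. The percentages were 41.8, 85.1 and 100 for control PF with PBS, and 49.3, 85.1 and 98.5 for TNBS PF with PBS. Unchanged genes made up 2.5%, 4.62% and 6.25% of the calls. In the real data 1117 and 1758 genes were called in TNBS PF against control PF and against PBS. The Benjamini-Hochberg adjustment depends on how many genes change, so the simulated percentages need not hold there. A list of oxidative phosphorylation genes shifted by 0.15 was called in each of the 3, and of 28 unshifted lists 0, 0 and 1 were called by camera. The simulated genes were drawn independently of each other, while the estimated correlation was 0.181 for the real oxidative phosphorylation list and 0.425 for ribosomal proteins. These list counts therefore cannot show how often camera calls unshifted lists of correlated genes.

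The alternatives were a pseudocount of 0.1, no filter, a filter at FPKM 5, TPM scaling, quantile and median-ratio normalization, a fit of only the 2 groups compared, no mean-variance trend, an absolute log2 fold change of at least 1, a replicate block, each library left out in turn, and for lists an estimated correlation and the rotation test fry. Fits of limma voom on recovered fragments and fragments thinned to equal depth with random seed 7 were added after the data had been seen. A fit of raw counts was not run, since the table holds FPKM. Trends with GC content and exon length were removed by loess with a span of 0.5. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.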

Results

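Gene expression was measured by RNA sequencing in 9 libraries of a mouse bone marrow mesenchymal stromal cell (MSC) line, an adherent cell with immunomodulatory secretion that the labels mark SV40. The cells had been kept for 24 h with peritoneal fluid (PF) of control mice, with PF of mice given TNBS for 3 days, or with phosphate-buffered saline (PBS). TNBS is a hapten used to induce colitis in rodents. Each group, named control PF, TNBS PF and PBS from here on, had 3 libraries. The labels give 10% serum for all of them, PBS included. The depth recovered from the deposited values was 19.8, 18.6 and 21.5 M assigned fragments in control PF 1 to 3, 25.1, 25.6 and 22.9 M in TNBS PF 1 to 3, and 17.9, 18.0 and 20.3 M in PBS 1 to 3. At these depths 1 fragment in a transcript of 1 kb corresponded to an FPKM between 0.0391 and 0.056.

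The 9 libraries separated by group on the leading components of the expression values, which held 34.8% and 15.7% of the variance. Pearson correlations of log2 values were 0.996 to 0.998 between libraries of a group and 0.994 to 0.996 between groups, across genes, which are not independent replicates. Of 21959 genes in the table, 10537 were tested. Nothing in the labels states that the 3 libraries of a group are separate cultures or separate fluid donors, so the p-values measure only the spread between these samples, which may be technical.

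**Figure D1:**
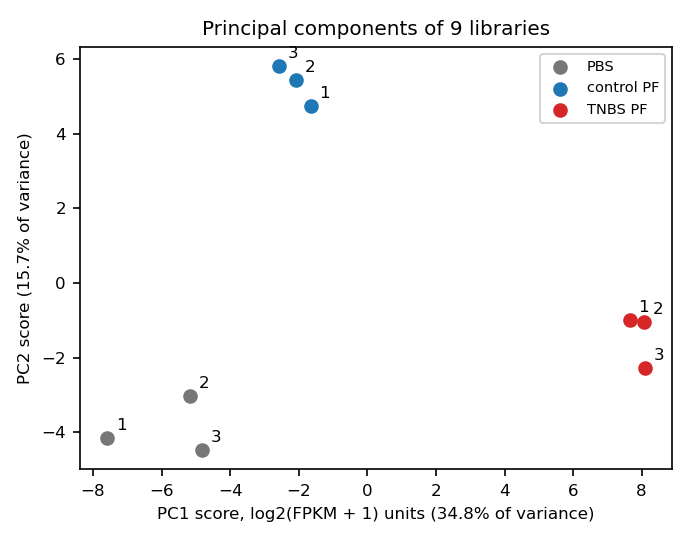
Scores of the 9 libraries on principal components 1 and 2 of log2(FPKM + 1), with the percentage of variance on each axis and replicate numbers beside the points. The 3 groups occupy separate areas, with TNBS PF at the right on component 1, which holds 34.8% of the variance.

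The series concerns MSC followed after transplantation into mice with colitis, and the comparison of TNBS PF with control PF asks how the cells differed with the TNBS treatment of the fluid donors. In TNBS PF the cells expressed 2.04-fold more Ccn2, which encodes connective tissue growth factor, a secreted matricellular protein (38.3 ± 0.918 against 18.8 ± 0.874 FPKM, SD, n = 3 each). Tfrc, the transferrin receptor that takes up iron, was 1.76-fold higher (47.1 ± 1.39 against 26.7 ± 0.555 FPKM). Genes of cholesterol synthesis were lower as a group, among them Idi1, an enzyme of the mevalonate pathway (53.4 ± 0.637 against 67.7 ± 1.26 FPKM). The fibrillar collagen gene Col3a1 was lower as well (26.9 ± 0.396 against 38.3 ± 1.02 FPKM). Ptgs2, which encodes the inducible enzyme of prostaglandin synthesis, rose from 78.6 ± 2.08 to 107.5 ± 3.44 FPKM.

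Ccn2 (ENSMUSG00000019997, mm10 chromosome 10, 24595442 to 24598683, plus strand) rose by 0.99 on the log2 scale (SE 0.0447, adjusted p = 5.64e-08). Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794, plus strand) rose by 0.79 (SE 0.0332, adjusted p = 4.47e-08). The largest other rises were in the cytokine gene Tslp (0.68, adjusted p = 0.000225), the immune receptor gene Tigit (0.67, adjusted p = 0.000219) and Tmem171 (0.66, adjusted p = 0.000654). Serpinb1a, which encodes a serine protease inhibitor, fell the most (−0.79, SE 0.0638, adjusted p = 1.26e-05). It was followed by Steap4, a metalloreductase gene (−0.62, adjusted p = 3.11e-06), and by the matrix gene Aspn and Igsf10 (both −0.58, adjusted p = 0.000176 and 5.5e-05). Saa3, an acute phase gene, fell from 113.3 ± 7.21 to 77.6 ± 8.33 FPKM (−0.54, adjusted p = 0.000269). Each of these genes had its 3 TNBS PF values on one side of all 3 control PF values.

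**Figure D2:**
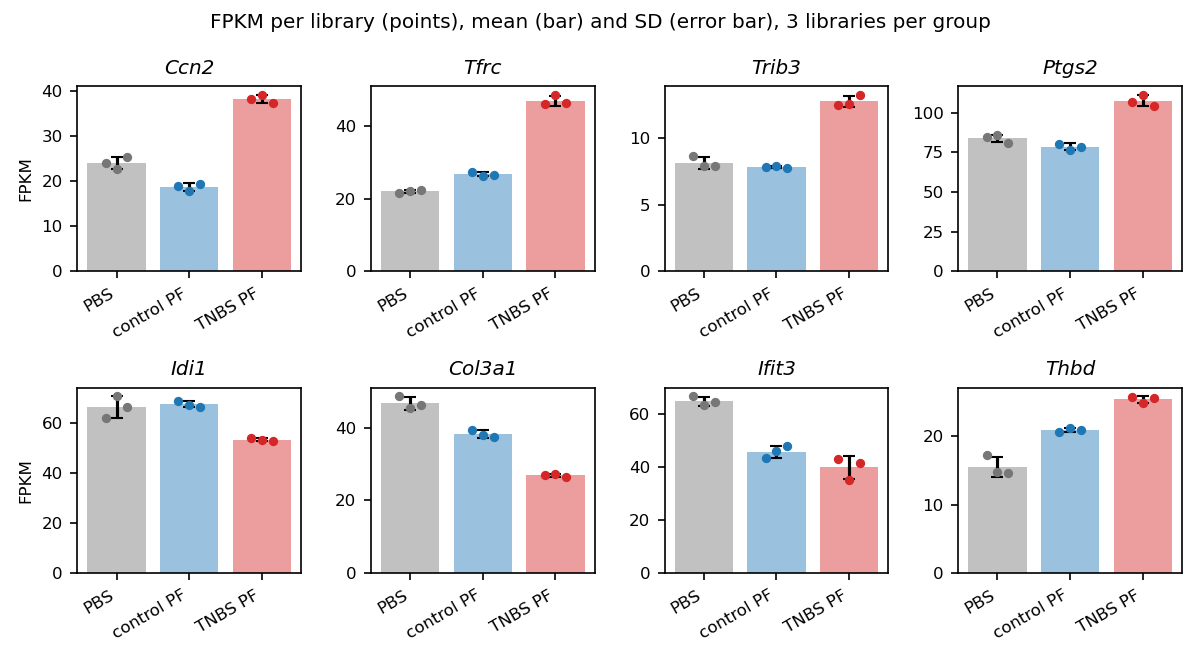
FPKM of 8 genes, chosen after their values were seen, in PBS, control PF and TNBS PF. Points are the 3 libraries of each group, bars are group means and error bars are SD. Ccn2 was 38.3 FPKM in TNBS PF, 18.8 in control PF and 24.1 in PBS, on axes that start at 0.

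Of the 26 tested genes of cholesterol synthesis and uptake, 20 fell and 0 rose in TNBS PF against control PF (24 fell, 0 rose adjusted over the list alone). Fdps (−0.44), Mvd (−0.38), Idi1 (−0.34) and Acat2 (−0.31) fell the most. The list had a median log2 fold change of −0.22 (camera adjusted p = 1.01e-18), and its call held with adjusted p = 0.0391 with an estimated correlation. Among 25 genes of the actin cytoskeleton and TGF-beta target list, 13 rose and 1 fell (16 and 2 adjusted over the list alone, median 0.17, camera adjusted p = 4.31e-12). Beside Ccn2, the secreted matricellular gene Ccn1 rose by 0.61 and Ankrd1, a nuclear ankyrin repeat gene, by 0.50, whereas the matrix gene Tgfbi fell by 0.47. This call also held, with adjusted p = 0.0488 with an estimated correlation.

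The integrated stress and unfolded protein response list had 14 of 35 members higher and 0 lower (14 and 2 adjusted over the list alone, median 0.02, mean 0.15). Trib3, a target of the transcription factor ATF4, rose by 0.64 and Chac1, a glutathione-degrading enzyme gene, by 0.62. The amino acid transporter genes Slc7a5 and Slc7a11 rose by 0.55 and 0.51. The camera adjusted p was 2.85e-06, and the call was lost at adjusted p = 0.0516 with an estimated correlation. Of 27 immediate early genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 0.000248), with Dusp5 at 0.48 and Myc at 0.30. That call was lost too, at adjusted p = 0.0516 with an estimated correlation. Of 28 p53 target genes, 6 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.08, camera adjusted p = 0.00481, adjusted p = 0.0606 with an estimated correlation). Aen (0.36) and Gadd45a (0.34) rose and Sesn1 fell by 0.23. Heat shock protein genes had 3 risen and 1 fallen of 23 (6 and 1 adjusted over the list alone, median 0.03, camera adjusted p = 0.0275, adjusted p = 0.311 with an estimated correlation). The mitochondrial chaperone genes Hspa9 (0.40) and Hspd1 (0.25) were among those that rose.

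Of 36 collagens and matrix proteins, 12 fell and 2 rose (14 and 3 adjusted over the list alone, median −0.09, camera adjusted p = 0.000278, adjusted p = 0.306 with an estimated correlation). Col3a1 (−0.49), Col6a1 (−0.32) and Col6a2 (−0.28) fell, whereas Col1a1 had a log2 fold change of −0.09 (adjusted p = 0.405). Complement and acute phase genes had 6 fallen and 1 risen of 14 (8 and 1 adjusted over the list alone, median −0.21, camera adjusted p = 4e-04, adjusted p = 0.23 with an estimated correlation). Saa3 and Cp, the ceruloplasmin gene, fell by 0.54 and 0.33. In the interferon gamma and antigen presentation list 7 of 26 fell and 0 rose (8 and 0 adjusted over the list alone, median −0.11, camera adjusted p = 0.000483, adjusted p = 0.117 with an estimated correlation). The guanylate binding protein gene Gbp2 (−0.34) and Iigp1 (−0.29) were 2 of the 7. Of 32 type I interferon response genes, 4 fell and 0 rose (9 and 0 adjusted over the list alone, median −0.04, camera adjusted p = 0.00863, adjusted p = 0.518 with an estimated correlation). Dhx58 fell by 0.25, while Isg15 had a log2 fold change of 0.01 (adjusted p = 0.858).

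Of 21 fatty acid oxidation and PPAR target genes, 7 fell and 0 rose (11 and 1 adjusted over the list alone, median −0.10, camera adjusted p = 0.00132, adjusted p = 0.0606 with an estimated correlation). Cpt1a, which controls fatty acid entry into mitochondria, fell by 0.35 and Pdk4 by 0.30. Of 8 adipogenic genes, 3 fell and 0 rose (5 and 0 adjusted over the list alone, median −0.20, camera adjusted p = 0.00115, adjusted p = 0.0698 with an estimated correlation), namely Fasn, Scd2 and Scd1. Of 34 lysosome and autophagy genes, 7 fell and 0 rose (8 and 0 adjusted over the list alone, median −0.07, camera adjusted p = 0.000947, adjusted p = 0.0955 with an estimated correlation), among them Ctsa (−0.20) and Ctsd (−0.18). Of 35 mitosis genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone, median −0.06, camera adjusted p = 0.00234, adjusted p = 0.0606 with an estimated correlation). Top2a fell by 0.16, and the proliferation marker Mki67 fell by 0.17 with an adjusted p of 0.0481 that ranged from 0.0023 to 0.162 over 17 alternatives. It was 0.0787, 0.162, 0.127, 0.0855 and 0.13 without control PF 2, control PF 3, TNBS PF 1, TNBS PF 2 and TNBS PF 3. The 43 ribosomal protein genes had 0 risen and 0 fallen, also adjusted over the list alone, by limma. Their median was 0.03 (camera adjusted p = 0.00738, adjusted p = 0.622 with an estimated correlation), and it was 0 under quantile normalization.

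Among the 14 tested lists that did not pass, adjusted p ranged from 0.099 to 0.916. Inflammatory cytokines and chemokines had 5 risen and 0 fallen of 22 (6 and 0 adjusted over the list alone, adjusted p = 0.099), with Lif (0.29) and Csf1 (0.28) beside Tslp. Their median was −0.05, while their mean was 0.06 and the test pointed higher. Il6 (−0.09, adjusted p = 0.61), Ccl2 (−0.08, adjusted p = 0.267), Cxcl12 (−0.06, adjusted p = 0.314), Tnfaip6 (−0.03, adjusted p = 0.727), Tgfb1 (0.04, adjusted p = 0.789) and Nfkbia (0.02, adjusted p = 0.831) did not pass. Stromal surface and identity markers had 3 risen and 4 fallen of 18 (4 and 5 adjusted over the list alone, adjusted p = 0.521). Their median of 0.003 differed in sign from their mean of −0.05 and from the test, and it turned negative under TPM and quantile scaling. The growth factor receptor genes Pdgfrb (−0.39) and Pdgfra (−0.38) and the stem cell antigen gene Ly6a (−0.32) fell, and Cd44 rose by 0.21. Among 31 iron handling and ferroptosis genes 3 rose and 6 fell (5 and 6 adjusted over the list alone, adjusted p = 0.706). Chemokine receptors and migration genes had 1 risen and 3 fallen of 19 (4 and 4 adjusted over the list alone, adjusted p = 0.916), with a median of 0.01 against a mean of −0.03 and a test that pointed lower. Nuclear encoded oxidative phosphorylation genes had 1 risen and 1 fallen of 35 (0 and 1 adjusted over the list alone, adjusted p = 0.548), with a median of 0.01, a mean of −0.001 and a test that pointed higher, and a negative median under quantile normalization.

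The counts of the remaining lists that did not pass were as follows, with risen genes given before fallen genes. NF-kB feedback and target genes had 2 and 3 of 22 (2 and 3 adjusted over the list alone, adjusted p = 0.306). Secreted immunomodulators of stromal cells had 1 and 3 of 22 (2 and 3 adjusted over the list alone, adjusted p = 0.367), with Ptgs2 the gene that rose and Hgf (−0.31) one that fell. Matrix proteases and inhibitors had 2 and 6 of 25 (4 and 8 adjusted over the list alone, adjusted p = 0.367), with Plaur at 0.46. NRF2 antioxidant response genes had 3 and 1 of 24 (3 and 1 adjusted over the list alone, adjusted p = 0.15), with Txnrd1 at 0.23. Hypoxia and glycolysis genes had 1 and 2 of 34 (1 and 2 adjusted over the list alone, adjusted p = 0.663). Glucocorticoid target genes had 1 and 2 of 16 (2 and 2 adjusted over the list alone, adjusted p = 0.706). DNA replication genes had 1 and 0 of 34 (0 and 0 adjusted over the list alone, adjusted p = 0.55). Osteogenic genes had 0 and 0 of 7 (0 and 1 adjusted over the list alone, adjusted p = 0.4), and the 12 mitochondrially encoded genes had 0 and 0 (adjusted p = 0.367).

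Of 14 markers of mesothelial cells, which line the peritoneal cavity, 4 were tested singly and 10 had a mean FPKM under 1 in PBS. The summed FPKM of the 14 was 52.7, 56.4 and 58.0 in the TNBS PF libraries and between 46.2 and 48.6 in the other 6 libraries. Msln carried most of the sum, with mean values of 42.2 FPKM in TNBS PF, 35.6 in control PF and 38.1 in PBS. Msln (0.24, adjusted p = 0.0043), Krt19 (0.59, adjusted p = 0.0154) and Krt18 (0.28, adjusted p = 0.0497) were called higher in TNBS PF than in control PF, and Slpi had a log2 fold change of −0.25 (adjusted p = 0.12). The adjusted p of Krt19 ranged from 0.00145 to 0.0823 over alternatives, with 0.0644, 0.0566, 0.0606 and 0.0703 without control PF 2, control PF 3, TNBS PF 1 and TNBS PF 2. That of Krt18 ranged from 0.0334 to 0.148, with 0.138, 0.0651, 0.0969, 0.117 and 0.148 without control PF 1, control PF 2, TNBS PF 1, TNBS PF 2 and TNBS PF 3. Msln, Krt18 and Slpi were chosen after their values were seen.

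By limma, 1117 of 10537 tested genes (10.6%) passed an adjusted p threshold of 0.05 in TNBS PF against control PF, 543 higher and 574 lower. Median-ratio scaling gave 679 higher and 442 lower. The median absolute log2 fold change of the 1117 was 0.21, and 1112 of them had groups that did not overlap. Among all tested genes 3351 (31.8%) had groups that did not overlap, where chance gives 10%. No gene reached an absolute log2 fold change of 1 by limma, a count of 0 also at an unadjusted p threshold of 0.05, where limma voom on recovered fragments gave 4. The 1 added to FPKM shrinks fold changes, and Ccn2, at 2.04-fold in FPKM, stayed under the limit. The count was 733 without control PF 2, 708 without control PF 3, 691 without TNBS PF 1, 661 without TNBS PF 2 and 676 without TNBS PF 3. Lists called by camera numbered 15 of 29, 6 higher and 9 lower, and 2 held with an estimated correlation, cholesterol synthesis and the actin and TGF-beta list.

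**Figure D3:**
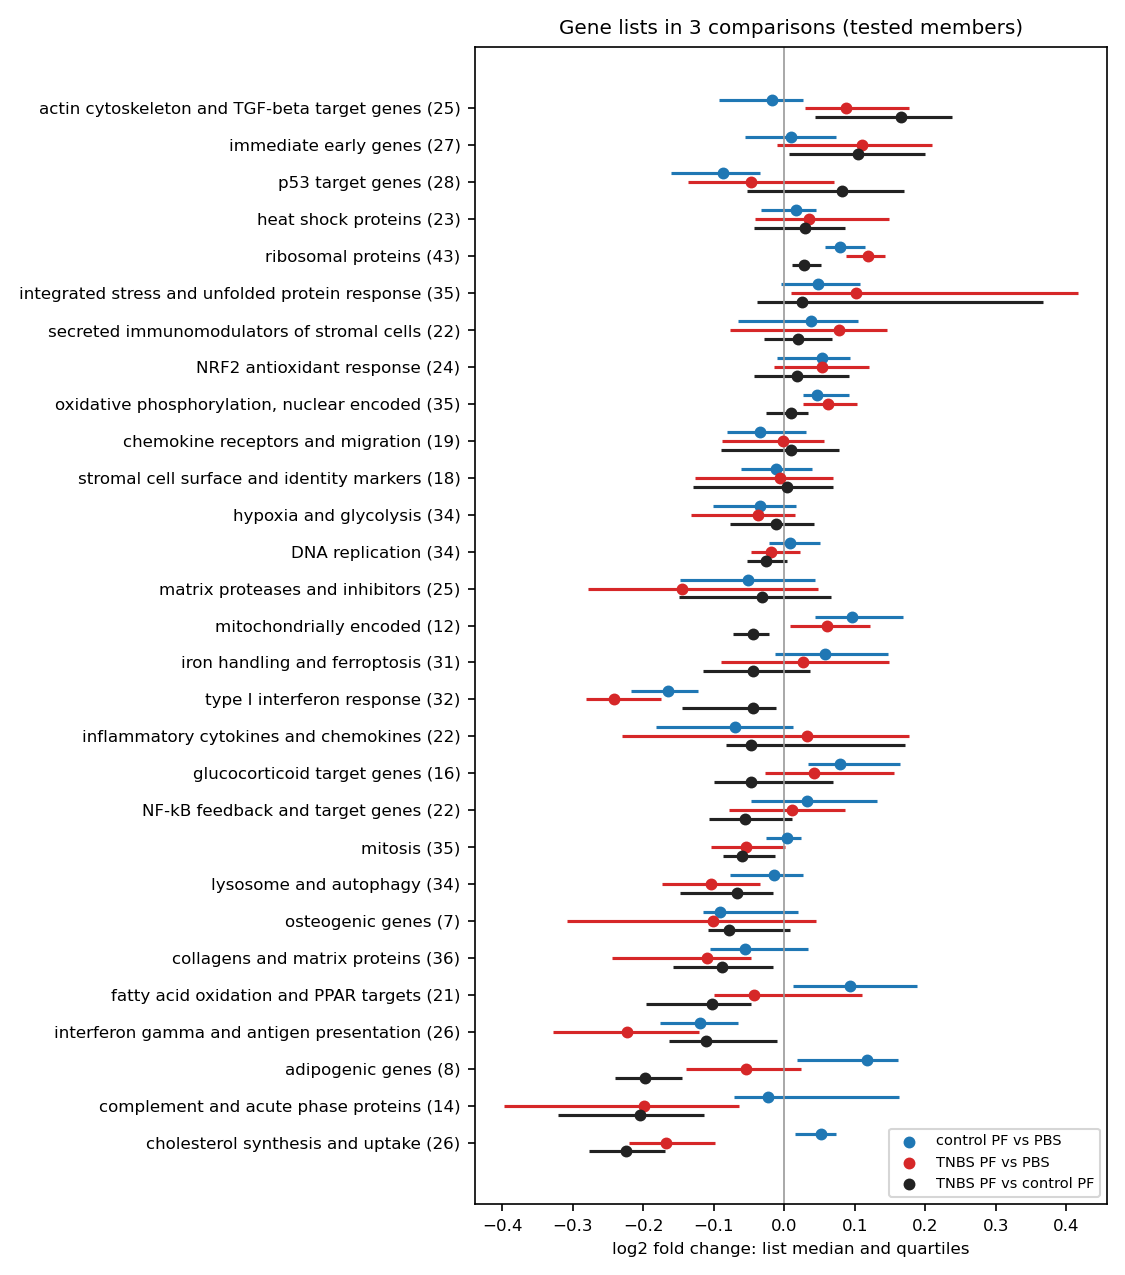
Median log2 fold change of each tested gene list (points) with the quartiles (lines) in the comparisons of the 3 groups, with the number of tested members in brackets. Cholesterol synthesis and uptake has its median at −0.22 in TNBS PF against control PF and at 0.05 in control PF against PBS.

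The comparison of control PF with PBS asks how cells kept with fluid of control mice differ from cells given PBS in its place. The labels give 10% serum for both groups. Genes induced by interferon were lower in control PF, among them Ifit3 (45.6 ± 2.22 against 64.7 ± 1.64 FPKM, SD, n = 3 each). The matrix and cytoskeleton genes Thbs1, encoding thrombospondin 1 (145.0 ± 3.24 against 196.0 ± 5.79 FPKM), and Acta2, encoding smooth muscle actin (194.6 ± 3.93 against 262.5 ± 3.32 FPKM), were lower too. Higher genes included Rdh10, a retinol dehydrogenase (11.0 ± 0.539 against 7.37 ± 0.637 FPKM), and Crabp2, a retinoic acid binding protein (97.5 ± 5.23 against 71.7 ± 2.2 FPKM). The endothelial anticoagulant gene Thbd was also higher (20.96 ± 0.307 against 15.6 ± 1.47 FPKM), as was Tnfaip6, a secreted anti-inflammatory hyaluronan binding protein (19.2 ± 0.643 against 15.5 ± 0.816 FPKM).

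Rdh10 rose by 0.53 (SE 0.0679, adjusted p = 0.00174), Crabp2 by 0.44 (SE 0.0447, adjusted p = 0.00043), Npr3 by 0.42 (adjusted p = 0.00321), Thbd by 0.41 (adjusted p = 0.0015) and Tubb3 by 0.39 (adjusted p = 0.00123). Igfbp3 fell the most of the genes with an established name (−0.72, adjusted p = 0.00317), from 1.76 ± 0.39 to 0.666 ± 0.0508 FPKM. Spon2 (−0.68, adjusted p = 0.000785), Postn (−0.56, adjusted p = 0.00234) and Aspn (−0.53, adjusted p = 0.0015), which encode matrix proteins, followed. Thbs1 and Acta2 both fell by 0.43 (SE 0.031 and 0.0316, adjusted p = 2.56e-05 each). Each of these genes had its 3 control PF values on one side of all 3 PBS values. The gene 2610528A11Rik (ENSMUSG00000096001), chosen after its value was seen, was the single gene past an absolute log2 fold change of 1 (−1.19, SE 0.172, adjusted p = 0.00321, 1.62 against 4.85 FPKM), with an adjusted p of 0.0501 without the filter, in a range over alternatives from 0.00021 to 0.0501. Limma voom gave 5 such genes.

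Of 32 type I interferon response genes, 12 fell and 0 rose in control PF against PBS (23 and 0 adjusted over the list alone), led by Ifit3 (−0.50), Mx2 (−0.33) and Ifit1 (−0.33). The list median was −0.17 (camera adjusted p = 8.1e-23, adjusted p = 0.0492 with an estimated correlation). Isg15 fell by 0.19 with an adjusted p of 0.0213 that ranged from 0.0058 to 0.092 over 17 alternatives and was 0.0877 without control PF 1 and 0.0757 without control PF 3. Of 26 interferon gamma and antigen presentation genes, 8 fell and 0 rose (15 and 0 adjusted over the list alone, median −0.12, camera adjusted p = 2e-11, adjusted p = 0.027 with an estimated correlation), with Igtp at −0.28. Of 28 p53 target genes, 3 fell and 0 rose (8 and 0 adjusted over the list alone, median −0.09, camera adjusted p = 4.52e-07, adjusted p = 0.0256 with an estimated correlation), namely Ephx1 (−0.31), Plk2 (−0.25) and Ccng1 (−0.16). The adjusted p of Ccng1 ranged from 0.0109 to 0.109 over alternatives, with 0.108, 0.0795 and 0.104 without control PF 1, 2 and 3 and 0.0708 and 0.0903 without PBS 2 and 3.

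Lists of iron and lipid handling were higher. Of 31 iron handling and ferroptosis genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.000204, adjusted p = 0.027 with an estimated correlation). Steap1 (0.32), Cp (0.30) and Tfrc (0.27) were among them. Of 21 fatty acid oxidation and PPAR target genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.09, camera adjusted p = 2.37e-05, adjusted p = 0.027 with an estimated correlation). Fabp5, a fatty acid binding protein gene, rose by 0.28 and Angptl4 by 0.25. Of 16 glucocorticoid target genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.08, camera adjusted p = 0.000473, adjusted p = 0.038 with an estimated correlation), Angptl4 and Errfi1 (0.20). These 3 lists, the 2 interferon lists and the p53 list were the 6 whose calls held with an estimated correlation.

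The other 11 list calls were lost with an estimated correlation. Ribosomal protein genes had 0 risen and 0 fallen of 43 by limma, but 15 and 0 adjusted over the list alone (median 0.08, camera adjusted p = 1.19e-13, adjusted p = 0.194 with an estimated correlation). The share of all 83 cytosolic ribosomal protein genes, a wider set, in the summed FPKM was 9.29% ± 0.0563 in control PF and 8.81% ± 0.26 in PBS (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest this design allows). Oxidative phosphorylation genes had 1 risen and 0 fallen of 35 (3 and 0 adjusted over the list alone, median 0.05, camera adjusted p = 0.00011, adjusted p = 0.224 with an estimated correlation). The 12 mitochondrially encoded genes had 0 risen and 0 fallen (2 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 0.00101, adjusted p = 0.265 with an estimated correlation), and the call was lost without PBS 1 at adjusted p = 0.0848, in a range over 11 alternatives from 5.13e-06 to 0.265. Collagens and matrix proteins had 1 risen and 8 fallen of 36 (2 and 11 adjusted over the list alone, median −0.06, camera adjusted p = 0.00018, adjusted p = 0.249 with an estimated correlation), with Fbln5 at −0.47 and Col12a1 at −0.44. The actin cytoskeleton and TGF-beta target list had 0 risen and 4 fallen of 25 (2 and 5 adjusted over the list alone, median −0.02, camera adjusted p = 0.00744, adjusted p = 0.224 with an estimated correlation). Ccn2 fell by 0.34 in it.

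Matrix proteases and inhibitors had 0 risen and 3 fallen of 25 in control PF against PBS (0 and 4 adjusted over the list alone, median −0.05, camera adjusted p = 0.00744, adjusted p = 0.224 with an estimated correlation), and without PBS 1 the adjusted p was 0.111 in a range from 0.00106 to 0.224. Inflammatory cytokines and chemokines had 1 risen and 2 fallen of 22 (2 and 6 adjusted over the list alone, median −0.07, camera adjusted p = 0.00843, adjusted p = 0.086 with an estimated correlation), and without control PF 3 the adjusted p was 0.0566 in a range from 0.00572 to 0.086. Cxcl5 rose by 0.34 and Cx3cl1 fell by 0.45. The integrated stress and unfolded protein response had 1 risen and 0 fallen of 35 (4 and 0 adjusted over the list alone, median 0.05, camera adjusted p = 0.00101, adjusted p = 0.116 with an estimated correlation). Cholesterol synthesis and uptake had 1 risen and 0 fallen of 26 (1 and 0 adjusted over the list alone, median 0.05, camera adjusted p = 0.0014, adjusted p = 0.194 with an estimated correlation). Adipogenic genes had 1 risen and 0 fallen of 8 (4 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 0.00744, adjusted p = 0.133 with an estimated correlation). The 24 NRF2 antioxidant response genes had 0 risen and 0 fallen, also adjusted over the list alone (median 0.05, camera adjusted p = 0.0385, adjusted p = 0.194 with an estimated correlation). Without control PF 3 and without PBS 1 their adjusted p was 0.0704 and 0.212, in a range from 0.011 to 0.212.

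The 12 lists that did not pass had adjusted p from 0.0508 to 0.877, the lowest for lysosome and autophagy genes (0 risen, 1 fallen of 34). Complement and acute phase genes had a median of −0.02 against a mean of 0.03 and a test that pointed higher (adjusted p = 0.826). Il6 (0.30, adjusted p = 0.111), Ptgs2 (−0.09, adjusted p = 0.195), Ccl2 (−0.05, adjusted p = 0.577), Col1a1 (−0.12, adjusted p = 0.375) and Mki67 (0.03, adjusted p = 0.847) did not pass.

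By limma, 227 of 10537 tested genes (2.15%) passed in control PF against PBS, 107 higher and 120 lower, with a median absolute log2 fold change of 0.24. TPM scaling gave 94 higher and 153 lower. All 227 had groups that did not overlap, as had 1965 (18.6%) of all tested genes, where chance gives 10%. At an unadjusted p threshold of 0.05 the count was 1643. It was 103 without the filter on low values, 117 without the mean-variance trend, 374 by limma voom, 115, 130 and 124 without control PF 1, 2 and 3, and 142 without PBS 3, and without PBS 2 it was split into 194 higher and 117 lower.

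The comparison of TNBS PF with PBS asks the same of the fluid of mice given TNBS. Tfrc was 47.1 ± 1.39 FPKM in TNBS PF and 22.1 ± 0.337 in PBS (SD, n = 3 each). Ifit3, a gene induced by interferon, was lower (39.8 ± 4.2 against 64.7 ± 1.64 FPKM). The fibrillar collagen gene Col3a1 was lower (26.9 ± 0.396 against 46.7 ± 1.73 FPKM). Asns, the asparagine synthetase gene, was higher (132.5 ± 6.51 against 92.7 ± 3.63 FPKM), as was Thbd (25.4 ± 0.459 against 15.6 ± 1.47 FPKM).

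Tfrc rose by 1.06 (SE 0.0332, adjusted p = 1.12e-09), Npr3, a natriuretic peptide receptor gene, by 0.80 (adjusted p = 4.38e-06), Tigit by 0.74 (adjusted p = 5.68e-05), and Cth, a cysteine synthesis gene, and Serpinb2 both by 0.71 (adjusted p = 1.75e-05 and 2.02e-05). Spon2 fell by 1.12 (SE 0.0771, adjusted p = 2.53e-06), Aspn by 1.10 (SE 0.0665, adjusted p = 8.65e-07), Igfbp3 by 1.04 (SE 0.103, adjusted p = 2.93e-05) and Cbr2 by 0.90 (adjusted p = 4.38e-06). Each of these genes had its 3 TNBS PF values on one side of all 3 PBS values. With Gm5617 (ENSMUSG00000042293, −1.03, adjusted p = 0.00362), chosen after its value was seen, Tfrc, Spon2, Aspn and Igfbp3 were the 5 genes past an absolute log2 fold change of 1, where limma voom gave 14.

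Of 32 type I interferon response genes, 27 fell and 0 rose in TNBS PF against PBS (28 and 0 adjusted over the list alone), with Ifit3 at −0.69, Ifit3b at −0.58 and Ifit1 at −0.48. The median was −0.24 (camera adjusted p = 4.34e-17), and the call was lost at adjusted p = 0.091 with an estimated correlation. Of 26 interferon gamma and antigen presentation genes, 17 fell and 0 rose (21 and 0 adjusted over the list alone, median −0.22, camera adjusted p = 5.86e-12), with Iigp1 at −0.47 and Gbp2 at −0.42. This call held with adjusted p = 0.0403 with an estimated correlation. The integrated stress and unfolded protein response had 14 risen and 0 fallen of 35 (17 and 1 adjusted over the list alone, median 0.10, camera adjusted p = 1.77e-10), and it held as well, with adjusted p = 0.0403 with an estimated correlation. Slc7a11 (0.63), Trib3 (0.59), the serine synthesis gene Psph (0.58) and Asns (0.51) rose the most.

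Of 43 ribosomal protein genes, 24 rose and 0 fell (33 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 1.41e-13, adjusted p = 0.172 with an estimated correlation), with Rps18 at 0.20, and the median was 0.06 with quantile normalization. The share of all 83 cytosolic ribosomal protein genes in the summed FPKM was 9.44% ± 0.105 in TNBS PF against 8.81% ± 0.26 in PBS (SD, n = 3 each, two-sided exact permutation p = 0.1). Cholesterol synthesis and uptake had 17 fallen and 0 risen of 26 (20 and 0 adjusted over the list alone, median −0.17, camera adjusted p = 2.37e-11, adjusted p = 0.0517 with an estimated correlation), with Mvd at −0.33, Idi1 at −0.31 and Insig1 at −0.29. Collagens and matrix proteins had 18 fallen and 1 risen of 36 (20 and 3 adjusted over the list alone, median −0.11, camera adjusted p = 4e-08, adjusted p = 0.149 with an estimated correlation), with Col3a1 at −0.77, Col12a1 at −0.64 and Col6a1 at −0.46. Lysosome and autophagy genes had 11 fallen and 0 risen of 34 (17 and 0 adjusted over the list alone, median −0.10, camera adjusted p = 2.91e-05, adjusted p = 0.075 with an estimated correlation). The actin cytoskeleton and TGF-beta target list had 8 risen and 3 fallen of 25 (11 and 3 adjusted over the list alone, median 0.09, camera adjusted p = 3.74e-05, adjusted p = 0.108 with an estimated correlation). Ccn2 (0.65), Ankrd1 (0.63) and Ccn1 (0.55) rose in it, and Tgfbi fell by 0.48.

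Immediate early genes had 7 risen and 0 fallen of 27 in TNBS PF against PBS (7 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.000973, adjusted p = 0.075 with an estimated correlation), with Phlda1 at 0.53. Oxidative phosphorylation genes had 3 risen and 0 fallen of 35 (3 and 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.000963, adjusted p = 0.285 with an estimated correlation). NRF2 antioxidant response genes had 7 risen and 0 fallen of 24 (8 and 2 adjusted over the list alone, median 0.05, camera adjusted p = 0.0125, adjusted p = 0.115 with an estimated correlation), with Txnrd1 at 0.31. Complement and acute phase genes had 2 risen and 7 fallen of 14 (3 and 8 adjusted over the list alone, median −0.20, camera adjusted p = 0.00673, adjusted p = 0.285 with an estimated correlation), with Saa3 at −0.45. Mitosis genes had 0 risen and 8 fallen of 35 (0 and 8 adjusted over the list alone, median −0.06, camera adjusted p = 0.0114, adjusted p = 0.108 with an estimated correlation). Mki67 had a log2 fold change of −0.14 (adjusted p = 0.0733).

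Heat shock protein genes had 7 risen and 1 fallen of 23 (9 and 2 adjusted over the list alone, median 0.03, camera adjusted p = 0.015, adjusted p = 0.252 with an estimated correlation). Without TNBS PF 1 and without PBS 1 their adjusted p was 0.0595 and 0.0502, in a range over alternatives from 0.00601 to 0.252. Matrix proteases and inhibitors had 2 risen and 9 fallen of 25 (2 and 10 adjusted over the list alone, median −0.15, camera adjusted p = 0.0181, adjusted p = 0.267 with an estimated correlation), with adjusted p = 0.0665 without PBS 1 in a range from 0.00541 to 0.267. Iron handling and ferroptosis genes had 9 risen and 2 fallen of 31 (11 and 7 adjusted over the list alone, median 0.03, camera adjusted p = 0.0497, adjusted p = 0.132 with an estimated correlation). Without TNBS PF 1 and without PBS 3 this adjusted p was 0.0595 and 0.131, in a range from 0.000203 to 0.135. The 13 lists that did not pass had adjusted p from 0.0737 to 0.95. Inflammatory cytokines and chemokines had a median of 0.03 against a mean of −0.02 and a test that pointed higher (adjusted p = 0.831), and NF-kB feedback and target genes a median of 0.01 against a mean of −0.02 and a test that pointed higher (adjusted p = 0.95). The first of these medians turned negative under quantile normalization and the other under TPM scaling. Ptgs2 rose by 0.36 (adjusted p = 2.02e-05) and Tnfaip6 by 0.27 (adjusted p = 0.00103), and Il6 had a log2 fold change of 0.22 (adjusted p = 0.122).

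By limma, 1758 of 10537 tested genes (16.7%) passed in TNBS PF against PBS, 822 higher and 936 lower, with a median absolute log2 fold change of 0.21. TPM scaling gave 624 higher and 1153 lower, and median-ratio scaling 1047 higher and 762 lower. Of the 1758, 1732 had groups that did not overlap, as had 3717 (35.3%) of all tested genes, where chance gives 10%. The count was 1148 without TNBS PF 3.

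Control PF and TNBS PF were compared with the same 3 PBS libraries. Of the genes called in both comparisons, 154 had the same sign, 59 higher and 95 lower, including Npr3, Thbd and Tfrc among the higher and Spon2, Postn, Aspn, Igfbp3, Col12a1 and Ifit3 among the lower. Independent lists of these sizes would share 8.35 higher and 10.7 lower genes. In 50 simulated sets of unchanged groups against shared controls the overlap was 0 in each, a value nearly fixed in advance where no gene is changed, so it does not measure what shared controls add to the overlap. The fold changes of the comparisons correlated with r = 0.535 across genes, which are not independent replicates, where simulated unchanged groups gave a mean of 0.5. Their covariance was 0.00712, against a simulated mean of 0.00195 and a range from 0.00179 to 0.00215. The 3 PBS libraries cannot be split into separate controls, so part of the overlap and of the covariance may come from shared controls.

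Opposite signs against PBS were called for 5 genes, named after their values were seen. Ccn2 had log2 fold changes of −0.34 in control PF and 0.65 in TNBS PF, Tslp −0.40 and 0.28, the tissue factor gene F3 −0.21 and 0.27, and the activin gene Inhba −0.22 and 0.20. Serpinb1a had 0.35 in control PF and −0.44 in TNBS PF. Their log2 fold changes in the direct comparison of the fluids, which follow from these values, were 0.99, 0.68, 0.48, 0.42 and −0.79.

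**Figure D4:**
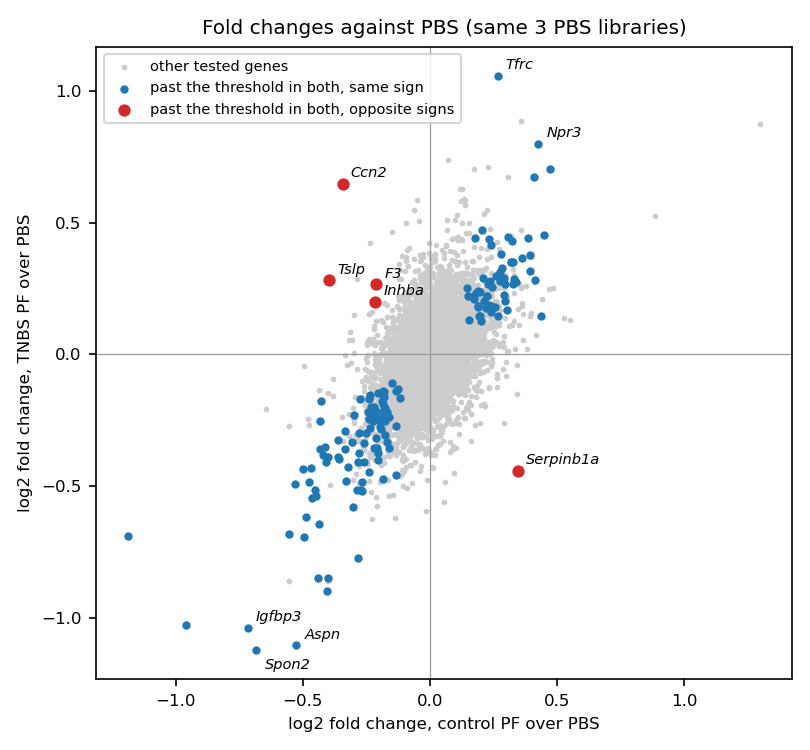
Log2 fold change of each tested gene in control PF over PBS (horizontal axis) and in TNBS PF over PBS (vertical axis), with genes called in both in colour. The 154 genes called with the same sign lie along the diagonal, and the 5 called with opposite signs are named.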

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

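The counts over splits, the thinned fragments for the gene count and the tests for carried-over cells were chosen only after the results were seen. The tests of the cholesterol and ribosomal patterns were chosen before their own outcomes were seen, but those patterns are themselves results of these data.

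The effects of the 2 fluids against PBS were called with opposite signs for 5 genes and 2 lists. For the genes the direct comparison of TNBS PF with control PF is the difference of these 2 effects, so after this choice it had to call them and adds no evidence of its own. Ccn2, whose product is a matricellular protein of wound repair, had a difference of 0.9922 on the log2 scale. The epithelial-type cytokine gene Tslp had 0.6792, the coagulation initiator gene F3 0.4771, the activin subunit gene Inhba 0.4157 and the protease inhibitor gene Serpinb1a −0.7876. The actin cytoskeleton and TGF-beta target list had a median difference of 0.165 (adjusted p = 0.0488 with an estimated correlation), while its calls against PBS were lost at adjusted p = 0.224 in control PF and 0.108 in TNBS PF with an estimated correlation. The cholesterol synthesis list had −0.224 (adjusted p = 0.0391 with an estimated correlation), while its calls against PBS were lost at adjusted p = 0.194 and 0.0517 with an estimated correlation. Opposite directions against PBS were thus not called for either list in that setting. With fry they were called, in control PF and TNBS PF at adjusted p = 0.0235 and 0.00072 for the actin list. For the cholesterol list fry gave 0.0348 and 0.000203. In single comparisons with PBS some of the gene calls depended on 1 library. Tslp in control PF had adjusted p = 0.0821 without control PF 2 and 0.0937 without control PF 3, in a range from 0.0127 to 0.123. F3 in control PF had 0.0918 without control PF 1, 0.0831 without control PF 2 and 0.0754 without PBS 1, in a range from 0.0175 to 0.0918. Inhba in control PF had 0.0568, 0.0521 and 0.0522 without control PF 2, control PF 3 and PBS 3, in a range from 0.00043 to 0.0572. Serpinb1a in control PF had 0.0687 without control PF 1, in a range from 0.00166 to 0.0785. Tslp in TNBS PF had 0.125, 0.08, 0.0931 and 0.119 without TNBS PF 1, TNBS PF 3, PBS 1 and PBS 3, in a range from 0.00301 to 0.125.

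The first pattern weighed is the 1117 genes called between TNBS PF and control PF, where TNBS PF libraries were deeper. After every library was thinned to equal depth 967 of them, 86.6%, were called again with the same sign, but random thinning leaves the expected FPKM as they were, so depth cannot be told apart from the group here. For carried-over blood or immune cells the summed FPKM of immune markers, 27.5, 24.6 and 23.7 in TNBS PF, 24.0 to 25.7 in control PF and 22.9 to 25.5 in PBS, decided nothing alone, but of 24 transcripts abundant in such cells, chosen after their levels were seen, 16 were at 0 in all TNBS PF libraries, among them S100a9, Tyrobp, Ptprc and Hbb-bs. The highest, Lyz2, was at 0.267 in 1 library and on average at 0.204 in TNBS PF, 0.179 in control PF and 0.207 in PBS. A share of 13.6% of carried-over RNA, which lowers a gene by the median called fall of 0.21, would give 1.36 if such cells held an assumed 10 FPKM. This argues against these cells at that share as the cause of the 574 falls as a set, and it does not cover the 543 rises. Cd14 and Cd68, which the cells also express in PBS (12.9 and 1.92 FPKM), were not among the 24. For mesothelial cells the marker sums were 52.7 to 58.0 in TNBS PF and 46.2 to 48.6 elsewhere, mainly from Msln, which the cells also express in PBS. The 10 markers under 1 FPKM in PBS summed to 0.388 to 0.462 in TNBS PF and 0.249 to 0.372 elsewhere, near the floor. Both sums were higher in every TNBS PF library than in every other library, which carried-over mesothelial RNA predicts. The second sum is too near the floor to decide. At a share of 13.6%, 1 such marker at an assumed 10 FPKM in mesothelial cells would alone give 1.36. Of the 10, Upk3b, Krt7 and Muc16 were at 0 in TNBS PF and the highest, Wt1, at 0.209 on average. Only if the assumed level holds does this argue against mesothelial cells at that share as the cause of the falls as a set. The level of these markers in mesothelial cells was not measured here. Smaller shares of them stay open, since Msln, Krt19 and Krt18 were called higher. Other cells stay open too (highest marker hardly expressed in PBS 0.843, for Lck, against up to 0.973 in control PF). So do causes of the rises, smaller shares behind single genes, the TNBS treatment and a difference in fluid composition or handling.

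For the counts of called genes, 10 splits of the 6 libraries exist for each comparison, so a share under 0.1 cannot be reached. The real split was the single 1 of 10 to reach its count in each comparison. It gave 1117 genes in TNBS PF against control PF, where the highest other split gave 0. It gave 227 in control PF against PBS, where the highest other gave 1, and 1758 in TNBS PF against PBS, where the highest other gave 0.

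The second pattern weighed is the lower expression of cholesterol synthesis genes in TNBS PF than in control PF, with a median log2 fold change of −0.224. After trends with GC content and exon length were removed the median was −0.215, with quartiles of −0.261 and −0.159 and 19 of 26 members past the threshold, which argues against these trends as the whole cause. A biological explanation, more sterol in the cells sensed by LXR, predicts higher LXR targets. The 5 tested of 11 LXR targets had a median of −0.164 with quartiles of −0.168 and −0.0811 by limma camera (p = 0.0672, direction lower, p = 0.111 with an estimated correlation). Mylip was at −0.35, Srebf1 at −0.17 and Arl4c in the other direction at 0.12. The call of Srebf1 (adjusted p = 0.0331) was lost at 0.116, 0.1, 0.115 and 0.118 without control PF 2, control PF 3, TNBS PF 1 and TNBS PF 3, in a range from 0.012 to 0.118. The predicted rise was not seen, but 5 genes whose test did not pass cannot decide against more sterol sensed by LXR. Sterol taken up without activation of LXR, a lower activity of SREBP for other reasons and the fluid of TNBS mice as such stay open, as untested.

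The third pattern weighed is the higher expression of ribosomal protein genes in TNBS PF than in PBS, with a median log2 fold change of 0.118 that was 0.0599 with quantile normalization. These genes are short, with a median length of 2050 bases against 4550 over all tested genes. After the trends with GC content and length were removed the median was 0.105 (camera adjusted p = 7.39e-12), which argues against these trends as the whole cause. After thinning to equal depth it was 0.117, and since thinning leaves the expected FPKM as they were, depth cannot be told apart from the group. The list call had adjusted p = 0.172 with an estimated correlation, and a difference in cell growth, fluid protein or RNA composition stays open, as untested.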

How the results depend on the processing

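The voom fits, the thinned fragments and most settings of the overlap were chosen only after the data had been seen.

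No named gene past the threshold reversed its direction under any alternative that was run, and among the lists the median of ribosomal proteins in TNBS PF against control PF went to 0 with quantile normalization. Over all called genes, quantile normalization changed the sign of 3 in TNBS PF against PBS. Requiring an absolute log2 fold change of at least 1 left 0 genes in TNBS PF against control PF by limma (0 also at an unadjusted p threshold of 0.05, 4 by voom), 1 in control PF against PBS (5 by voom) and 5 in TNBS PF against PBS (14 by voom), and it left 0 genes called in both comparisons with PBS. Most called changes were smaller than that, and the 1 added to FPKM shrinks them further by construction.

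Control PF against PBS gave 103 genes without the filter, 117 without the mean-variance trend and 374 by voom, against 227. The overlap of the 2 comparisons with PBS, 154 genes, was 70 without the filter, 83 without the trend and 259 by voom. The cause was not tested. With 1 library left out, the counts ranged from 661 to 860 in TNBS PF against control PF, from 115 to 311 in control PF against PBS and from 1148 to 1620 in TNBS PF against PBS, and without each of the 3 PBS libraries the overlap ranged from 103 to 213. These fits have fewer samples. TNBS PF against control PF gave 1064 genes with quantile normalization, 1067 with TPM, 1121 with median-ratio scaling, 1037 after thinning and 1549 by voom.

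With an estimated correlation between genes, 2 lists stayed past the threshold in TNBS PF against control PF, 6 in control PF against PBS and 2 in TNBS PF against PBS, against 15, 17 and 16 with the preset correlation of 0.01. Some lists lost in TNBS PF against control PF had estimates near or under 0.01. These were immediate early genes (0.0103), fatty acid oxidation and PPAR targets (0.0103), mitosis (0.00844) and p53 targets (−0.0103). The size of the correlation does not account for their loss. With the correlation estimated, camera also reads its statistic with the few residual degrees of freedom of the 9 libraries. This raises p at an unchanged correlation. How far it accounts for the loss of each list was not tested. Besides that setting, the ribosomal call in TNBS PF against control PF was lost with quantile normalization (0.548), with fry (0.337) and without control PF 3 (0.0608), in a range from 0.00117 to 0.622. In the same comparison the type I interferon list had 0.0637 without control PF 2 and 0.174 without TNBS PF 2, in a range from 0.000312 to 0.518, and heat shock proteins 0.0608 without control PF 3 and 0.114 without TNBS PF 1, in a range from 0.00938 to 0.311.

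Of the named genes past the threshold, 78 of 101, 35 of 73 and 91 of 119 were past it in every setting run in the 3 comparisons. Among the 24 largest changes, 2, 10 and 1 were lost in at least 1 setting. In TNBS PF against control PF Krt19 had an adjusted p of 0.0644, 0.0566, 0.0606 and 0.0703 without control PF 2, control PF 3, TNBS PF 1 and TNBS PF 2, in a range from 0.00145 to 0.0823. Fgf21 had 0.0782, 0.0505 and 0.0763 without control PF 3, TNBS PF 2 and TNBS PF 3, in a range from 0.00289 to 0.0799. The 10 in control PF against PBS were Camk2n2, Sprr1a, Serpinb6b, H1f10, Ptpn5, Acot1, Ackr3, Ndufa4l2, Neurl3 and Gjb2. In TNBS PF against PBS Cyp1b1 had 0.0652, 0.0551 and 0.0884 without TNBS PF 1, 2 and 3, in a range from 0.000735 to 0.117.

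With the replicate block the counts were 906, 169 and 1537, and the overlap was 114. Correlations of residuals between libraries of the same number were −0.0978 to 0.0746 and between different numbers −0.075 to 0.0776, so the numbers do not pair the libraries. Depth limits genes of low expression, since an FPKM of 0.0391 to 0.056 is 1 fragment in 1 kb.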

Other observations

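The comparison with the authors' calls was chosen only after the data had been seen, while the tests of annotation terms and the marker lists were planned.

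In TNBS PF against control PF, of 106 tested genes of ribosome biogenesis, which builds the ribosome from RNA and protein, 39 rose and 1 fell (median 0.11, camera adjusted p = 1.66e-14, adjusted p = 0.682 with an estimated correlation). Aminoacyl-tRNA biosynthesis, which charges tRNA with amino acids, had 14 risen and 0 fallen of 44 (camera adjusted p = 1.19e-08, adjusted p = 0.682 with an estimated correlation). The cellular amino acid biosynthetic process had 12 risen and 0 fallen of 21 (median 0.18, camera adjusted p = 3.63e-08, adjusted p = 0.682 with an estimated correlation). The response to bacterium, a term of defense genes, had 18 fallen and 2 risen of 85 (camera adjusted p = 0.00026, adjusted p = 0.703 with an estimated correlation). Over 2261 terms, camera called 47 higher and 28 lower in TNBS PF against control PF, 28 and 18 in control PF against PBS, and 46 and 32 in TNBS PF against PBS. With an estimated correlation 0 terms passed by camera in each of the 3 comparisons. That setting has few residual degrees of freedom and was adjusted over 2261 terms, so few terms could pass in it. The count of 0 does not show that correlation between genes made the calls.

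Macrophage and monocyte markers had a summed FPKM of 19.2 to 21.6 in control PF, 20.2 to 22.5 in TNBS PF and 17.7 to 19.3 in PBS, with Cd14 the highest gene. Neutrophil markers summed to 2.76 to 3.2, 2.36 to 3.47 and 4.16 to 4.5, with Mmp9 the highest gene. Among single markers, chosen after their values were seen, Mmp9 had a log2 fold change of −0.08 in TNBS PF against control PF (adjusted p = 0.608). It fell by 0.46 in control PF against PBS (adjusted p = 0.0178, range 0.00293 to 0.0946). In TNBS PF against PBS Mmp9 fell by 0.55 (adjusted p = 0.0013). Cd14 (0.19, adjusted p = 0.03, range 0.0204 to 0.121), Gata6 (0.25, adjusted p = 0.0317, range 0.00677 to 0.125), Krt19 (0.50, adjusted p = 0.0258, range 0.00398 to 0.105), Krt18 (0.32, adjusted p = 0.0204, range 0.00679 to 0.0826) and Msln (0.14, adjusted p = 0.0459, range 0.00943 to 0.181) were called higher there. Each of these 5 calls was lost without single libraries, for Cd14 at 0.121 without TNBS PF 1, for Gata6 at 0.125 without TNBS PF 1, for Krt19 at 0.104 without TNBS PF 2, for Krt18 at 0.0718 without TNBS PF 3 and for Msln at 0.181 without TNBS PF 3. B and plasma cell markers summed to 0.302 to 0.827 over the 9 libraries, T and NK cell markers to 0.525 to 1.01, and erythroid markers to 0.0569 to 0.36. Mast cell and eosinophil markers summed to 0.152 to 0.807, endothelial markers to 1.19 to 1.6 and intestinal epithelium markers to 0.805 to 1.4.

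In the authors' deposited table, 61 genes were called between TNBS PF and control PF, 42 between control PF and PBS and 88 between TNBS PF and PBS. These calls all had p under 0.05 and an absolute log2 fold change of at least 1, a fold limit that the limma counts above did not use. Without a fold limit, 1071, 170 and 1347 genes were under 0.05 after Benjamini-Hochberg adjustment of the deposited p-values. Of the 61, 42 and 88 calls in the authors' deposited table, 58, 37 and 73 had a mean FPKM under 1 in both groups. Over all 61, 42 and 88 calls the median was 9.5, 8 and 11 fragments per library. Of the calls in the authors' deposited table, 3, 5 and 13 passed the filter on low values and were tested, and 3, 4 and 13 of these were also called by limma. For the genes called by limma, the log2 fold changes in the authors' deposited table had the sign of the difference of mean FPKM for 1117 of 1117, 227 of 227 and 1758 of 1758. This was fixed in advance, since those log2 fold changes are close to the log2 ratio of the same means, and it is no separate evidence.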
